A study of Oncorhynchus mykiss with 20 samples.

How the data were processed

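RNA from cultured rainbow trout hepatocytes was measured on 20 Agilent arrays with 1 colour, Cy3. Cells were seeded at 500000 per ml, kept at 15 degrees C for 24 h and then exposed for 48 h, and labelled from 0.6 ug RNA, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The description field of the control samples names 30 nM EE2, while their titles and source names give control, and the latter were used.

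Spot intensity values were produced by the authors with Feature Extraction 10.7.1.1 and protocol GE1_107_Sep09, per the file headers. The processed intensity is background-subtracted and detrended within an array, and not scaled between arrays, per the file headers. The 0 or 1 flags for background, saturation and outliers come from the same software. A table of log2 values, also deposited by the authors, lists 45134 probes, with column medians from -0.0169 to 0.0161. How it was normalized is not given in the sources used here. In 77.7% of its rows exactly 1 array is at 0, and 9822 rows hold no 0. A probe with exactly 1 array at 0 appears centred on 1 of its own values, not necessarily on the same array throughout. Its columns followed quantile-normalized log2 processed intensities centred per probe most closely of 5 versions tried, with a median r of 0.936, a median slope of 0.981 and a median absolute difference of 0.125. This sets the log2 scale and the direction, and leaves the normalization unknown. The table was used as an alternative only.

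Each array has 62976 spots, of which 1319 control spots were left out, for 55468 probes. Spots marked as outliers, 6 to 44 per array, were set to missing, and 0 spots were saturated. The log2 processed intensity minus the array's 75th percentile was averaged over the spots of a probe. A probe counted as well above background on an array when at least 50% of its spots did, and was tested when it did so on 3 or more arrays of at least 1 group. Spots repeated 10 times on an array had a median SD of 0.0598 to 0.174 on the log2 scale, depending on the array.

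Comparisons used limma 3.58.1 in R 4.3.3: 1 model with group means over all 20 arrays, moderated tests of each concentration against control and of neighbouring concentrations, an F-test, and a linear term over the ordered groups scored 0 to 4. Calls have a Benjamini-Hochberg adjusted p under 0.05. Sets of probes were tested with fry on arrays other than those used to choose them, except that the variance of the choosing model drew on all arrays. Main settings and most alternatives were fixed before the data were examined. The alternatives were other background correction, scaling, filters, blocks, spread estimates, the authors' value table, the groups compared alone, and each array left out. Blocking on array sets, leaving out slide 4 and scaling on the spike-in control probes were added after seeing the data. Normexp was planned on mean spot signals, a column not used here, and was run on median spot signals with an offset of 50.

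On simulated data with 200 changed probes among 33062, the 30 nM comparison recovered 0% of changes of 1.5-fold, 6.0% of 2-fold, 44.0% of 4-fold and 78.0% of 8-fold, with 3 false calls among 67. The simulation had no array sets, whose spread is part of the SDs it used. Smaller changes are therefore mostly missed in these comparisons.

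The files give probe and target identifiers without gene names, and 0 target names matched the gene table of assembly USDA_OmykA_1.1. The 31 gene lists fixed beforehand, and the members of the vitellogenin, egg envelope and estrogen receptor lists, could therefore not be analysed here. The naming rule allowed at most 2 unnamed probes in each direction, and the probe with the largest fitted rise and the deepest fall at each concentration was taken among those called, with all 4 EE2 arrays on 1 side of the control mean and above background on the brighter side.

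Slide and scan day were read from the file headers. There were 4 slides and 2 scan days. Replicate numbers followed slide order in all 5 groups.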

Results

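Primary hepatocytes, the parenchymal cells of the liver, were isolated from juvenile rainbow trout and cultured for 48 h with ethynylestradiol (EE2), a synthetic estrogen used in contraceptive pills. The study asked how EE2 changes transcript levels across the genome, with concentrations rising in 10-fold steps from 0.03 to 30 nM against a solvent (DMSO) control. Each of the 5 groups held 4 arrays described as biological replicates, 20 arrays in all. Neither donor fish nor cell isolation is named for any array, so the p-values measure the spread between these arrays, whatever its source. The number of probes well above background ranged from 25864 to 40080 of 55468 per array, with a median of 32017. The control arrays averaged 32448 ± 811 (SD, n = 4) such probes and the 30 nM arrays 33911 ± 5088 (SD, n = 4). The 75th percentile of the signal ranged from 57.5 to 135 intensity units, and the number of arrays limits the precision of every value. After dim probes were left out, 33151 probes were tested. The files pair no probe with a gene name, so responses are described by probe and by concentration.

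At 30 nM EE2, 277 probes rose and 30 fell against solvent control. The median fall was -1.47 on the log2 scale, and the deepest was -2.84. Of the probes that rose, 57 were not well above background on any control array. Their rises are therefore known only as lower bounds, and the fitted values rest on control values too dim to measure. For 1 of these probes the bound gave no rise. The median rise was 2.43 as fitted and 2.20 with these 57 at their bounds. Among the 185 that were well above background on all 8 arrays, probe CUST_1658_PI426552878 rose most, by 6.92 with a standard error of 0.426 (limma adjusted p = 9.51e-08), a 121-fold change. Leaving out 1 array at a time gave rises of that probe from 6.38, without control replicate 3, to 7.14. Probe CUST_4589_PI426552878, whose transcript is not named in the files, has no rank beside it. It was not well above background on any of the 4 control arrays and was well above it on all 4 arrays at 30 nM, at least 82.3-fold brighter (limma adjusted p = 0.000585). The bound was 10.4-fold under normexp, which adds an offset of 50 to every signal, 35.1-fold without slide 4, 53.7-fold without 30 nM replicate 3 and 145-fold without replicate 2. Such a bound sets the mean of the bright group against a control mean in which each dim value is replaced by the lowest signal well above background on that array, where that is higher. The deepest fall was that of probe CUST_30495_PI426552878, from a log2 level of 3.16 ± 0.288 (SD, n = 4) in control to 0.318 ± 1.18 (SD, n = 4), a change of -2.84 with a standard error of 0.451 (limma adjusted p = 0.00195). With slide as a block, 175 probes rose and 25 fell. The number of falls was 14 under median scaling, 47 under quantile normalization and 63 with scan day as a block, where rises were 78.7% of the calls. It was 10 without control replicate 1 or without control replicate 2, 12 without 30 nM replicate 3 and 5 in a fit on these 2 groups alone, where 166 rose. Without replicate 3 of the 30 nM group, 188 probes passed the test in all.

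All these changes are relative to the bulk of the probes on an array. Centring the arrays instead on 8 spike-in control probes, a choice made after seeing the data, put the median probe at 30 nM 0.51 below control (log2 difference -0.51), and at 0.03 nM at -0.70. With this scaling 63 probes rose and 11 fell at 30 nM, 71 of them called in both ways. At 3 nM 22 rose and 2 fell, and at 0.3 nM 6 rose and 0 fell. The spike-in level relative to the bulk of the probes averaged -0.50 ± 0.45 (SD, n = 4) in control and 0.07 ± 0.58 (SD, n = 4) at 30 nM. The 30 nM arrays on slide 4, which held no control, were at 0.25 and 0.81. Those on slide 3 were at -0.43 and -0.35, below the control there at -0.22. Control replicate 2 was at -1.15. The shift at 30 nM thus went the other way on slide 3 and cannot be told apart from slide.

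Within a slide, 30 nM could be compared with control on slide 3 alone, with 2 EE2 arrays and 1 control array. All 277 probes that rose were higher there, with a median log2 difference of 2.17, and all 30 that fell were lower, with a median of -1.28. Slide 3 is among the arrays on which these probes were called, so this is no independent test. The same holds for the comparisons within slides at 3 and 0.3 nM, and within sets of arrays, given below. Medians within slides and sets, and of the same probes at other concentrations, are of fitted values and take in probes that were dim in control. Slide 4, the only slide scanned on the second day, held 2 of the 30 nM arrays and no control. Without its 5 arrays, 122 probes rose and 14 fell at 30 nM, with 2 arrays left in that group.

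At 3 nM EE2, 89 probes rose and 5 fell. The median rise was 2.71 on the log2 scale as fitted, and 2.56 with the 17 probes that were not well above background on any control array at their bounds. For 1 of these 17 the bound gave no rise. Among the 62 that were well above background on all 8 arrays, probe CUST_1658_PI426552878 rose most, by 6.70 with a standard error of 0.426 (limma adjusted p = 1.65e-07). Its log2 level went from 2.64 ± 1.08 (SD, n = 4) in control to 9.34 ± 0.250 (SD, n = 4). That is a 104-fold change. Leaving out 1 array at a time gave log2 rises from 6.16, without control replicate 3, to 6.92. Of the 5 falls, 2 were not well above background on any 3 nM array, so their depth is known only as a bound. Probe CUST_9379_PI426552878 had the deepest fall as fitted, -2.40 with a standard error of 0.458 (limma adjusted p = 0.0224). Its call was lost with slide as a block, where the change was -2.45, under normexp, where it was -1.02, with the replicate block, where it was -2.40, without slide 4, where it was -2.38, and with spike-in scaling, where it was -2.99. It was kept in 15 of the 20 fits that each left out 1 array, and lost without 3 nM replicates 1, 2 or 4 or control replicates 1 or 3. On slide 2, which held 3 arrays at 3 nM and 2 controls, all 89 probes that rose were higher, with a median of 2.76, and all 5 that fell were lower, with a median of -2.25. Blocking on slide gave 102 rises and 10 falls. The number of falls was 39 with array weights, 31 without slide 4, 9 without 3 nM replicate 4, 3 without control replicates 1, 2 or 4 in turn and 1 without control replicate 3. In a fit on the control and 3 nM arrays alone 50 probes rose and 0 fell.

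At 0.3 nM EE2, 14 probes rose and 0 fell. The median rise was 3.19 on the log2 scale, also with 1 probe at its bound. Among the 13 that were well above background on all 8 arrays, probe CUST_1658_PI426552878 again rose most, by 5.75 with a standard error of 0.426 (limma adjusted p = 2.17e-06), a 53.7-fold change. Its rise lay between 5.21, without control replicate 3, and 5.96 when 1 array at a time was left out. The 14 probes were higher on slide 1, with 1 array of each group and a median of 2.75, and on slide 3, with 2 EE2 arrays and 1 control and a median of 3.24. With slide as a block, 7 probes rose and 0 fell. In a fit on the control and 0.3 nM arrays alone 6 rose and 0 fell. The count was 9 without replicate 3 of the 0.3 nM group and 9 without replicate 4 of the control group.

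At 0.03 nM EE2, 0 probes passed the limma test, and 585 had an unadjusted p under 0.05, below the 1658 that chance would give with independent arrays. The arrays were not independent, and this fit counts the spread between the array sets given below as noise. With those sets as a block 2152 had such a p, from p-values that are too small. Neither number therefore measures how many probes changed. Probe CUST_1658_PI426552878 had a log2 level of 3.74 ± 0.788 (SD, n = 4), against 2.64 ± 1.08 (SD, n = 4) in control (limma adjusted p = 1). The count was also 0 with slide as a block. As no probe was called, no set of probes could be followed within slides.

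**Figure D1:**
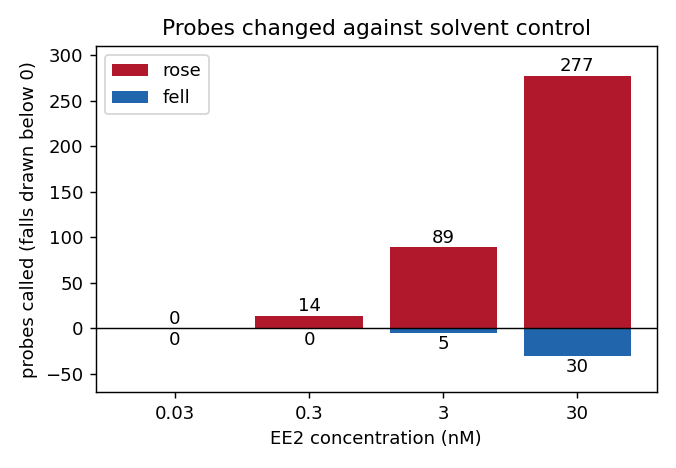
Number of probes called against solvent control (vertical axis, falls drawn below 0) at each EE2 concentration in nM (horizontal axis), with rises in red and falls in blue. Calls go from 0 at 0.03 nM to 277 rises and 30 falls at 30 nM.

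The lists of probes that rose at different concentrations overlapped. All 14 probes that rose at 0.3 nM also rose at 30 nM, where independent lists would share 0.117, and 87 of the 89 that rose at 3 nM did so, where independent lists would share 0.744. Of the 5 probes that fell at 3 nM, 2 also fell at 30 nM. The comparisons share their control arrays, which adds to such overlaps. Across the 33151 probes, fold changes at 3 and 30 nM correlated with r = 0.69, against 0.504 for simulated unchanged groups sharing 1 set of controls. Their covariance was 0.185, against 0.138 in the simulation, the only one of 6 pairs of concentrations above its simulated value. The simulation drew arrays independently and left out the sets of arrays that cross the groups, whose spread is shared by all groups, so its values are no exact no-change level. With the controls split 2 and 2, the correlation had a median of 0.225 over 6 splits. Each control array lies in a different set, so a split leaves opposite set differences in the fold changes compared. That pushes r down, so split values are no exact no-change level either. For 0.03 and 0.3 nM, where 0.03 nM had no calls, r was 0.661 against 0.503 in the simulation, and -0.0597 with split controls. For 0.3 and 30 nM it was 0.651 against 0.501, and 0.104 with split controls. For 0.03 and 30 nM, r was 0.423, against 0.501 in the simulation, with a median of -0.0465 when the controls were split. Probes are not independent replicates, and no p-value was taken from these correlations.

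The median response of the probes called at 30 nM was larger at 0.3 than at 0.03 nM, and larger at 3 than at 0.3 nM. No set test covered the step from 3 to 30 nM. The 277 probes that rose at 30 nM had a median log2 difference from control of 0.25 at 0.03 nM, 0.77 at 0.3 nM and 1.70 at 3 nM, values that share the control arrays used to choose the probes. Tested on arrays outside that choice, the same probes were higher at 0.3 than at 0.03 nM by a median of 0.54, with 92.1% of them higher (fry adjusted p = 0.00774 over 6 tests). They were higher at 3 than at 0.3 nM by 0.85, with 96.4% higher (fry adjusted p = 0.00702). The 30 probes that fell at 30 nM were lower at 0.3 than at 0.03 nM by a median of -0.48 (fry adjusted p = 0.00168) and lower at 3 than at 0.3 nM by -0.68 (fry adjusted p = 0.00702). The fry tests had no slide term. Of the 3 nM arrays 3 were on slide 2, which held no array at 0.3 nM. Only slide 4 held both groups, with 1 array of each, so the step from 0.3 to 3 nM can hardly be told apart from slide. For 0.03 nM against control, 277 probes chosen by their rise from 0.3 nM to the mean of 3 and 30 nM had a median difference of 0.08, against 0.07 for all probes (fry adjusted p = 0.645). That choice used no call threshold and disfavours probes that had largely risen by 0.3 nM. It therefore says little about a response of such probes at 0.03 nM. The fry test asks whether a set moves one way on balance and does not compare it with other probes.

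**Figure D2:**
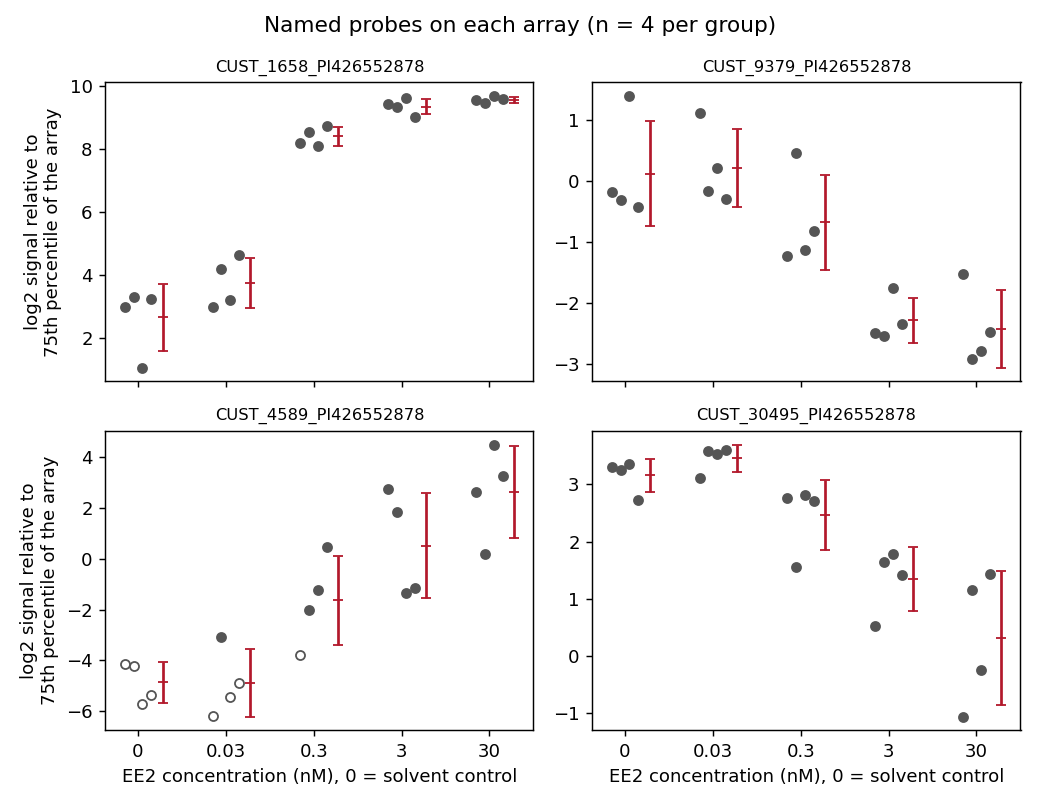
Log2 signal relative to the 75th percentile of the array (vertical axis) against EE2 concentration in nM (horizontal axis, 0 for solvent control) for the 4 named probes. Circles are arrays, open where the probe was not well above background, and red marks give the mean and SD of 4 arrays. CUST_1658_PI426552878 goes from a mean of 2.64 in control to 9.55 at 30 nM.

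Single steps of concentration called few probes. Between 0.03 and 0.3 nM, 9 probes rose and 0 fell, with a median rise of 3.42, also with 1 probe at its bound. Between 0.3 and 3 nM, 1 probe rose, by 1.96, and the call was lost in 14 of the 20 fits that each left out 1 array. Between 3 and 30 nM, 0 probes passed the limma test, and 1162 had an unadjusted p under 0.05, also below 1658. With the array sets given below as a block 4000 had such a p, again from p-values that are too small, and 0 were called. Blocking on slide gave 9, 0 and 0 for the 3 steps, and fits on only the 2 groups compared gave 1, 0 and 0. Probe CUST_1658_PI426552878 had a level of 9.34 ± 0.250 (SD, n = 4) at 3 nM and 9.55 ± 0.0964 (SD, n = 4) at 30 nM. Probe CUST_4589_PI426552878 was well above background on 3 of 4 arrays at 0.3 nM and on all 4 at 3 nM, where it was at least 18.9-fold brighter than control (limma adjusted p = 0.0277). That call was lost with slide as a block, under normexp, with the replicate block and with spike-in scaling. The fitted log2 changes there were 4.76, 2.02, 5.38 and 4.79, against 5.38 in the main fit, all resting on dim control values. The bound was 3.82-fold under normexp, 11.3-fold without 3 nM replicate 1 and 28.9-fold without replicate 3. The call was kept in 14 of the 20 fits that each left out 1 array, those without 3 nM replicates 1 or 2 or any control array losing it.

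Over all concentrations, 205 probes changed in the F-test, and 618 had a linear trend over the ordered groups, 494 of them rising and the rest falling. These counts were 177 and 482 with slide as a block, and 87 and 233 with spike-in scaling. In the trend, 490 rose and 254 fell with scan day as a block, and 489 rose and 196 fell under quantile normalization. With spike-in scaling 146 rose and 87 fell, and under median scaling 361 rose and 82 fell.

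Arrays also differed in a way the groups do not explain. After the group means were removed, the 20 arrays fell into 4 sets of 5, each with 1 array of every group. Pairs of arrays in the same set correlated with a mean r of 0.556 across probes, and pairs from different sets and groups with a mean of -0.182. The sets follow neither the replicate numbers nor the slides. In the sets, the probes that rose at 30 nM had median rises of 2.64, 2.29, 1.85 and 2.90, each from 1 EE2 and 1 control array. With the sets as a block, a choice made after seeing the data, 1636 probes rose and 495 fell at 30 nM, 393 rose and 182 fell at 3 nM, 37 rose at 0.3 nM, and 0 changed at 0.03 nM. All 307 probes called without the block at 30 nM were among those called with it. Such overlap was largely built in and is no independent check. Each set holds 1 array of every group, so the block leaves the fold change of a fully measured probe unaltered. The sets were found from the values that were tested, so the p-values with this block are too small.

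**Figure D3:**
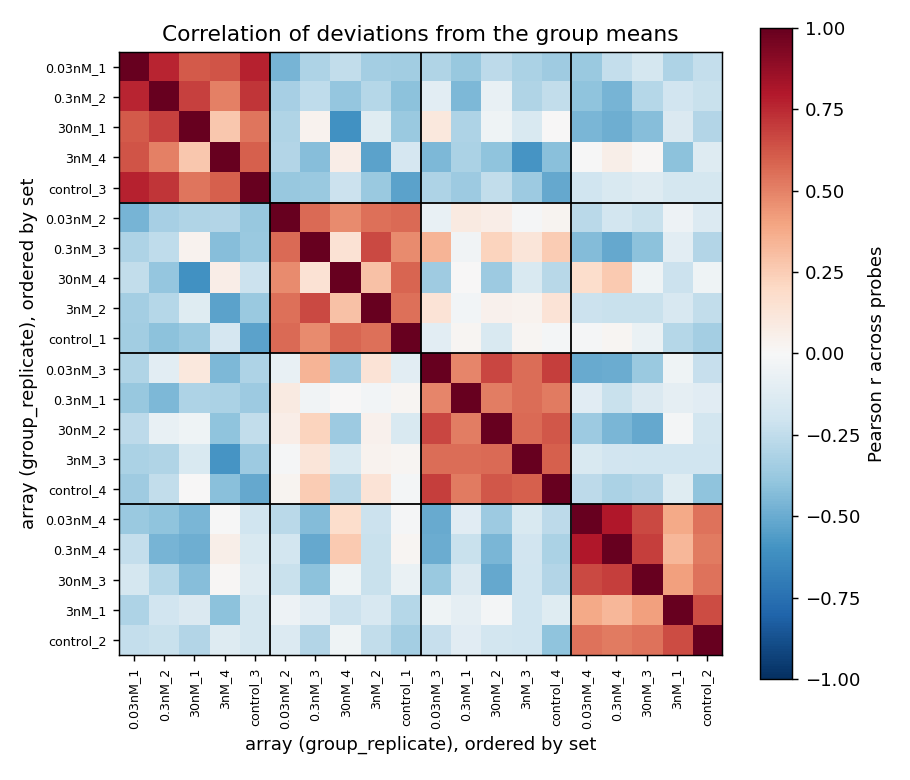
Pearson correlation across probes of each pair of the 20 arrays, after the mean of each group was removed, with arrays (named by group and replicate) on both axes ordered by set and black lines between the 4 sets. Pairs within a set have a mean r of 0.556.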

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

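The tests of spike-in amount, of scaling and of dim probes were chosen after their results were seen.

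Of 35 groups of 4 values checked, 5 had an array far from its group, where chance gives about 1.75 with independent arrays. Of the 5 values, 4 lie on arrays of 1 of the array sets found from the values, set 1, and arrays of a set vary together. Probe CUST_1658_PI426552878 was at 1.04 on control replicate 3, with the other controls from 2.98 to 3.29. Probe CUST_9379_PI426552878 was at 1.39 on the same array, with the others from -0.43 to -0.18. Probe CUST_30495_PI426552878 was at 2.74 on control replicate 4, with the others from 3.26 to 3.36. It was at 3.11 on replicate 1 of the 0.03 nM group, with the others from 3.54 to 3.61, and at 1.55 on replicate 2 of the 0.3 nM group, with the others from 2.71 to 2.82.

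A control probe for a spiked-in transcript, (+)E1A_r60_a107, brightened with EE2, a signal outside the probes compared. Its log2 level was -3.38 ± 0.539 (SD, n = 4) in control and -0.0717 ± 1.04 (SD, n = 4) at 30 nM, a difference of 3.31. It was well above background on 2 of the 4 control arrays and on all 4 at 30 nM. It was singled out as the control probe with the largest change of 56, the next being 1.42, so no p-value is given. More spike-in RNA would raise the 9 other E1A probes alike, and their median change was 0.576 and the largest 1.42, below the smallest difference of this probe between a 30 nM and a control array, 1.62. A local artefact is argued against by 100% of its 35 spots being brighter. A candidate explanation is a transcript of the cells binding the probe: its deviations followed 1 called probe with r = 0.951, and the best of as many random probes was as high in 5 of 1000 draws. Called probes may share array differences in response that random probes lack, so this stays a hypothesis.

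Rises were 90.2% of the calls at 30 nM. Under quantile, median, normexp and spike-in scaling the lowest share was 84.6%, so no scaling run removed the excess among the calls. The first 3 centre on the bulk of the probes. With spike-in scaling the median probe was at -0.51, a difference that cannot be told apart from slide. A shift shared by most probes therefore stays open. The share was 76.8% with the array sets as a block and 68.2% with sets and slide. Among the calls of probes above the median level in control rises were 85.3%, which argues against dim probes that cannot fall further. A biological preference for induction stays open as a hypothesis.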

How the results depend on the processing

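The alternatives with array sets, without slide 4 and with spike-in scaling were chosen after seeing the data, and the others before. The 0 calls at 0.03 nM held under every alternative run. Rises outnumbered falls at 0.3, 3 and 30 nM under every alternative with calls there.

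The count at 0.3 nM, 14, became 9 with a replicate block, 7 with slide as a block, 6 with only the groups compared, 37 with the array sets as a block and 9 without slide 4. The count at 3 nM, 94, became 205 with array weights, 50 with only the groups compared, 575 with the sets and 989 with sets and slide together. At 30 nM, 307 became 200 with slide as a block, 171 with only the groups compared, 2131 with the sets, 1702 with sets and slide, and 136 without slide 4. The F-test's 205 became 308 with array weights, 1395 with the sets, 1417 with sets and slide, and 127 without slide 4. The trend's 618 became 210 with an added fold of 1.5, 382 on the 16 EE2 arrays with log10 concentration, 2828 with the sets, 2901 with sets and slide, and 342 without slide 4. The 9 probes between 0.03 and 0.3 nM became 1 with only the groups compared, 16 with the sets and 17 with sets and slide. The 1 probe between 0.3 and 3 nM became 0 under median scaling, no filter, replicate block, slide block, the authors' value table and only the groups compared, and 15 with array weights, 28 with the sets, 2 with sets and slide and 8 without slide 4. The 0 between 3 and 30 nM became 1 with sets and slide. Spike-in scaling gave 6 at 0.3 nM, 24 at 3 nM, 74 at 30 nM, 87 in the F-test, 233 in the trend and 0 between 0.3 and 3 nM. Fewer arrays were fitted with only the groups compared, without slide 4 and on the 16 EE2 arrays, where the scale changed too. The added fold removes calls by construction. For the others the cause was not tested.

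Leaving out each array gave 9 to 14 probes at 0.3 nM, 67 or more at 3 nM, always within 1.5 times of 94, 188 to 348 at 30 nM, 142 to 248 in the F-test, 424 to 715 in the trend, and 7 to 10, 0 to 4 and 0 to 1 for the 3 steps. The lowest count at 30 nM came without replicate 3 of that group.

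Replicate numbers do not pair the arrays. Same-numbered arrays of different groups had deviations with a mean r of -0.0862, from -0.419 to 0.803, and 2 of 20 arrays were closest to an array of their own number. With the replicate block, the counts at 3 and 30 nM were 71 and 228.

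With the controls split 2 and 2, the correlation of fold changes was -0.0597 for 0.03 and 0.3 nM, -0.175 for 0.03 and 3 nM, -0.0465 for 0.03 and 30 nM, -0.0379 for 0.3 and 3 nM, 0.104 for 0.3 and 30 nM and 0.225 for 3 and 30 nM. Splitting removes the shared controls by construction. It also sets the concentrations against controls of different array sets, which pushes r down, below 0 where nothing else is shared. Median scaling moved the median of all probes at 0.03 nM to 0.22. Of 556 values of the named probes, 24 lost and 5 gained a call, and 0 changed sign with a call in either fit. The 556 include values with no call in the main fit, where a change of sign was not counted. Probe CUST_30495_PI426552878 at 0.03 nM, for example, was at 0.30 in the main fit and at -0.47 with spike-in scaling. The gene list alternatives and other probes of a gene were not run, as no gene names were available here.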

Other observations

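The tests of slide as the whole source and of a shared source were chosen after seeing the data.

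The 4 sets of arrays were found again from odd-numbered and from even-numbered probes alone. Only 22 of 10000 random relabellings of the arrays gave 4 sets with 1 array of each relabelled group. With slide as a term 34 of the 40 pairs within sets were found again, so the sets were not recovered whole. Of 10000 random sets with 1 array of each group 0 shared as many pairs, 28 at most, which argues against slide as the whole source. Slide as a part of it stays open: pairs in different sets had a mean r of -0.036 on 1 slide, from -0.379 to 0.341, and of -0.219 on different slides. With the number of probes above background as a term, all 40 pairs were found again. A shared source of the cells, such as 1 isolation or fish per set, is a candidate explanation: 0 of 100 random blocks with 1 array of each group per block called as many probes at 30 nM as the sets, 430 at most against 2131. The labels name no source, and sets found from the values raise such a count by construction, so a source cannot be told apart from another factor shared by 5 arrays.

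Chance as the source of the counts at 0.3, 3 and 30 nM is argued against and not excluded. Of the 35 splits of each 8 arrays, 1, the real one, gave as many probes, 14, 94 and 307. The highest other splits gave 0, 0 and 1. With 35 splits, the real one can be no rarer than 1 in 35. The other splits mix EE2 and control arrays, so probes that respond to EE2 spread more there and low counts are partly built in. The same held for 0.3 against 0.03 nM, with 9 probes against 0. For 3 against 0.3 nM 1 of the 35 splits, the real one, called 1 probe and the others 0, which says little of a single call that most fits leaving out 1 array lose. For 0.03 nM and for 30 against 3 nM the real count was 0, so all 35 splits gave as many, with at most 0 and 5. Of 100 groupings of the 20 arrays, the real one counted among them, 3 gave at least 205 probes in the F-test. Counted in the same way, 2 gave at least 618 in the trend. The highest others gave 2512 and 2992, several times the real counts, which points to a structure of the arrays.

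No kind of target name passed Fisher's exact test for more or fewer calls at 30 nM, and the smallest of 4 adjusted p was 0.303.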
